A study of Mus musculus with 2 samples.

How the data were processed

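PolyA-selected RNA from mouse placenta was measured by RNA sequencing in 2 libraries of 1 group. Per the labels, each library was made from a single placenta of strain B6NCrl, the 2 placentas are separate biosamples listed under the same donor entry, and the libraries carry biological replicate numbers 1 and 2. The labels state RNA longer than 200 bases, adult stage, female sex and an age of 8 weeks. They do not state the gestational stage or whether both placentas came from 1 dam, so the spread between the libraries may be technical as well as biological. The stated stage, sex and age may describe the dam and not the placentas.

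For each library the authors deposited 1 table of genes and 1 table of transcripts. Per the file listings that accompany them, both were quantified from transcriptome alignments to mouse assembly mm10 with annotation M4. The column names are those RSEM writes, but the names and versions of the aligner and the quantifier, and the strand setting, were not given in the sources used here. The deposited expected counts are estimated reads that need not be whole, and 319 and 285 genes had fractional reads. The deposited TPM and FPKM values were scaled by the authors over every row of a table, control sequences included. The file headers also name posterior means of the counts and TPM with credibility bounds and posterior SDs in reads. The deposited percent columns give each transcript's share of its gene's TPM. Effective length was 35 bases below transcript length. FPKM values and credibility bounds were not used here.

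The tables also hold rows that name no mouse gene. The row for phiX174, a bacteriophage genome used as a sequencing control, held 154466 of 183853 reads in replicate 1 (84.0%) and 149953 of 173559 reads in replicate 2 (86.4%), and 52.2% and 60.7% of the deposited TPM. The 26248 tRNA rows held 52 and 19.99 reads. The 96 rows of ERCC spike-in RNA held 0 reads in both libraries, although the labels list spike-ins as used. These rows were left out of library sizes and tests, and TPM was rescaled to the same total over the 43346 Ensembl gene rows. Symbols and positions came from GENCODE release M21 on the same assembly, which matched 42462 genes. Members of the fixed lists matched except for 1 of 339 entries.

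The remaining gene reads numbered 29335 and 23586. A single read was worth 34.1 and 42.4 CPM, and a median of 15.5 and 22.2 TPM over protein-coding genes with a read. A gene with 0 reads could hold up to 3 reads, or 0.0102% and 0.0127% of gene reads. Shares above 0 have exact Clopper-Pearson 95% intervals, and a share of 0 is given the limit of 3 reads instead. Intervals and limits cover counting error only, because reads without molecular identifiers are not independent molecules.

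With 1 group there was no comparison between conditions. Levels are given as mean ± SD of the 2 libraries or as reads in each. Expected counts were rounded, and genes with at least 10 reads summed over both libraries were compared by a two-sided exact binomial test against TMM-scaled library sizes, with Benjamini-Hochberg adjustment at 0.05 and a ratio of at least 2. This test compares the 2 libraries, not conditions, and has no replicate check. Ratios of single genes had 0.5 reads added to each library, and ratios against 0 reads are given as bounds against 3 reads. The biological coefficient of variation came from edgeR's estimateDisp with an intercept only. Correlations across genes used log2(TPM + 1) over genes at 1 TPM or more in either library. For each list, the median log2 ratio of replicate 2 over replicate 1 (CPM with a prior of 0.5) was placed among 10000 random lists of the same size matched on mean expression. A log2 ratio shifted by 0.27 for every gene when total counts replaced TMM, and by 0.15 with median-of-ratios size factors.

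The design, the 33 lists and the rule for named genes were fixed before the data were examined. The rule took the 25 genes of highest mean TPM outside the mitochondrial genome, the 4 highest members of each list and any member below 1 TPM in both libraries, the 10 largest ratios in each direction among differing genes with at least 50 reads in the higher library, and all Y-linked and X inactivation genes. For isoforms it took Flt1, Igf2 and the 10 list genes of highest mean TPM whose second transcript held at least 10% of the gene's TPM in both libraries. The lists were the prolactin family, pregnancy-specific glycoproteins, placental cathepsins, spongiotrophoblast and glycogen cells, syncytiotrophoblast and labyrinth progenitors, trophoblast stem cell and giant cell regulators, decidual stroma, uterine natural killer cells, myometrium, uterine epithelium, yolk sac endoderm, erythroid cells with adult or embryonic globins, endothelium, fibroblasts and pericytes, macrophages and neutrophils, platelets, lymphocytes, paternally and maternally expressed imprinted genes, nutrient transporters, steroidogenesis, angiogenic factors, proliferation, hypoxia response, immediate early genes, skeletal muscle, pancreas, adipocytes, Y-linked genes, X inactivation RNA, histones and mitochondrial genes.

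The comparison was tested on simulated data drawn from the real profile and library sizes with 200 genes changed. These 200 were drawn only from genes with at least 20 reads summed, so the shares called do not cover genes with fewer. The comparison called 26.3% of 99 genes changed 2-fold and 85.7% of 98 genes changed 8-fold in the right direction, and 3 of 628 unchanged genes. With no change in mean but a simulated coefficient of variation of 1, it called 40.5% of 809 genes. Of 100 unshifted random lists of 12 genes with a read, 6 fell outside the central 95% of matched lists. Their log2 ratios were drawn from a normal distribution without the many zeros of the real ratios, so lists with unread members were not covered. A simulated coefficient of variation of 1 was recovered as 0.925 over 479 genes, and one of 0.2 as 0.187 over 625 genes.

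Alternatives covered the detection threshold, posterior mean TPM, share of counts instead of TPM, pseudocount, filters on low values, DESeq2 size factors and dispersions, total counts as library sizes, the minimum ratio, the prior, and each replicate left out. Alternatives with deposited TPM including phiX174, with genes of at least 10 reads for the correlation, with genes that share no read with another gene (posterior SD of 0 in both libraries) and with a prior worth 1 read were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, bedtools 2.31.1 and blastn 2.17.0 were used.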

Results

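PolyA-selected RNA of 2 mouse placentas was profiled, 1 library from each, to describe the transcripts of the organ. The libraries form 1 group with replicates 1 and 2, so the comparisons are between transcripts and between the 2 libraries, and no condition was compared. The gene tables held 183853 and 173559 reads in all, of which 29335 (16.0%) and 23586 (13.6%) were assigned to mouse genes and nearly all others to the phiX174 sequencing control. At least 1 read fell on 4903 and 4830 of 21474 protein-coding genes (22.8% and 22.5%), at least 10 reads on 329 and 282 of all 43346 genes, and at least 100 reads on 25 and 20. In both libraries, 2807 genes reached 1 TPM, which at this depth lay below the worth of a single read.

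Transcripts of trophoblast, the epithelial lineage of the placenta, were among the most abundant by mean TPM over the 2 libraries. Of the 25 genes with the highest mean TPM outside the mitochondrial genome, 12 belonged to 4 lists of trophoblast genes fixed beforehand. These were the pregnancy-specific glycoproteins Psg21, Psg16 and Psg20, the prolactin-family hormones Prl7d1, Prl2c5, Prl2b1, Prl2c2, Prl3b1 and Prl8a9, the spongiotrophoblast proteins Tpbpa and Tpbpb, and the protease Ctsj. Psg21 alone had 1778 and 329.6 reads (42184 ± 42747 TPM, SD, n = 2). Most of the 12 differed between the libraries, for example Psg20 (165 and 10112 TPM) and Prl2b1 (10862 and 746 TPM). The 25 genes of highest mean TPM with mitochondrial genes included, which are not the same 25, held 38.5% ± 12.4 of all TPM (SD, n = 2). Their share was 47.2% in replicate 1 and 29.7% in replicate 2. Of the 25 outside the mitochondrial genome, another 4 were nuclear copies of mitochondrial genes (Gm28437, Gm28438, Gm28661 and Gm10925), and 2 were the adult alpha globins Hba-a1 and Hba-a2. The remaining 7 were Gm42418, a noncoding gene on chromosome 17 (39846958 to 39848788) with 954 and 2431 reads, ENSMUSG00000045999, for which the annotation used gave no name, with 1703 and 0 reads, the elongation factor gene Eef1a1 with 338 and 52.7 reads, the cytoskeletal genes Actg1 (7.22 and 70.9 reads) and Arpc1b (8 and 38 reads), the antisense RNA Gm15564 (0 and 111 reads) and the pseudogene Gm2830 (0.80 and 89.9 reads). Of these 25 genes, each taken alone, 14 were higher in replicate 2, 8 were higher in replicate 1, and 3 (Psg16, Prl2c5 and Prl3b1) did not pass the comparison of the libraries. The 14 include Gm10925 and Gm28661, which with the identical mt-Atp6 and mt-Co2 had more reads in replicate 1, and Gm42418, and the 8 include ENSMUSG00000045999, so the tally depends on how reads were assigned. Nuclear protein-coding genes held 68.1% and 76.1% of gene reads, and the 83 ribosomal protein genes held 0.832% and 0.920%.

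Pregnancy-specific glycoproteins, secreted trophoblast proteins of the immunoglobulin superfamily, took the largest share of gene reads of any list as counted, although mitochondrial genes with their 7 nuclear copies added held more (14.1% and 4.82%). Their 13 genes lie on chromosome 7 between 17074040 and 18821607 (mm10), and all 13 had reads. They held 2383 reads in replicate 1 (8.12%, 95% interval 7.81 to 8.44%) and 1118 in replicate 2 (4.74%, 4.47 to 5.02%). Psg20 (5.81 and 249 reads), Psg28 (22.9 and 175) and Psg17 (20.8 and 53.7) were higher in replicate 2, while Psg21, Psg23 (125 and 9.05) and Psg26 (12.1 and 0) were higher in replicate 1. The other 7 did not differ beyond the threshold, among them Psg16 with 183 and 140 reads (7491 ± 275 TPM, SD, n = 2) and Psg18 with 94.8 and 48.5. Psg21 made up 74.6% of the list's reads in replicate 1 and 29.5% in replicate 2.

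The prolactin family of placental hormones held nearly the same number of reads in both libraries, 683 (2.33%, 2.16 to 2.51%) and 662 (2.81%, 2.60 to 3.02%), but from different members. Its 23 genes lie on chromosome 13 between 12790816 and 28151611, and 17 had a read in at least 1 library. Prl7d1, known as proliferin-related protein, had 15 and 245 reads, Prl7a2 had 3 and 78, and Prl2c2 had 33.3 and 115, all higher in replicate 2. Prl2b1 (229 and 11 reads) and Prl8a9 (162 and 17) were higher in replicate 1. Prl3b1, placental lactogen II, had 103 and 55 reads and Prl2c5 had 108 and 80.7, and neither passed. Prl3d1, Prl3d2 and Prl3d3, the placental lactogen I genes, and Prl5a1, Prl6a1 and Prl2c3 had 0 reads in both libraries. Prl2c2 and Prl2c3 share reads, with a posterior SD of 28.6 reads for Prl2c2 in replicate 2, so their split was uncertain.

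Spongiotrophoblast and glycogen cell genes were the trophoblast list whose share differed most between the libraries, at 237 reads (0.808%, 0.709 to 0.917%) and 1018 reads (4.32%, 4.06 to 4.58%). Tpbpa, a marker of spongiotrophoblast on chromosome 13 (60938492 to 60941984), had 18.6 and 666 reads, a 35.2-fold ratio, and its neighbour Tpbpb had 26.4 and 197. Ceacam11 went the other way (44 and 6 reads), and Ceacam14 (48.1 and 35), Ceacam12 (19 and 32), Flt1 (61 and 66) and Ceacam13 (11.9 and 8) did not pass. Gjb3 and Ascl2 had 0 reads. Placental cathepsins, cysteine proteases of trophoblast encoded on chromosome 13 between 61000179 and 61570127, held 121 reads (0.412%, 0.342 to 0.493%) and 253 (1.07%, 0.945 to 1.21%). Of these, Ctsj was higher in replicate 2 (42 and 198 reads), Ctsm was higher in replicate 1 (17.4 and 2.36), Cts3 (28.6 and 26.6) and Ctsq (29 and 17) did not pass, and Cts7 and Cts8 had 0 reads.

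The list of regulators and keratins of trophoblast stem and giant cells held 197 reads (0.672%, 0.581 to 0.772%) in replicate 1 and 40 (0.170%, 0.121 to 0.231%) in replicate 2, of which its 4 keratins held 176 and 37. Krt18, a keratin of simple epithelia, had 118 and 13 reads and Krt7 had 12 and 0, and both were lower in replicate 2. Krt8 (31 and 20 reads) and Krt19 (15 and 4) did not pass, and the 9 regulators, 21 and 3 reads in sum with Gata3 at 6 and 1, were each too thinly read to be compared. The stem cell regulators Cdx2, Eomes, Elf5 and Esrrb had 0 reads in both libraries, which was not distinguishable at this depth from shares of up to 0.0102% and 0.0127%. Syncytiotrophoblast and labyrinth genes held 29 reads (0.0989%) and 62.9 (0.266%). Gjb2, the gap junction protein connexin 26, had 2 and 40 reads and was higher in replicate 2, Tfrc, the transferrin receptor, had 10 and 5, Dlx3 2 and 4, Ovol2 1 and 1, and Met 0.

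**Figure D1:**
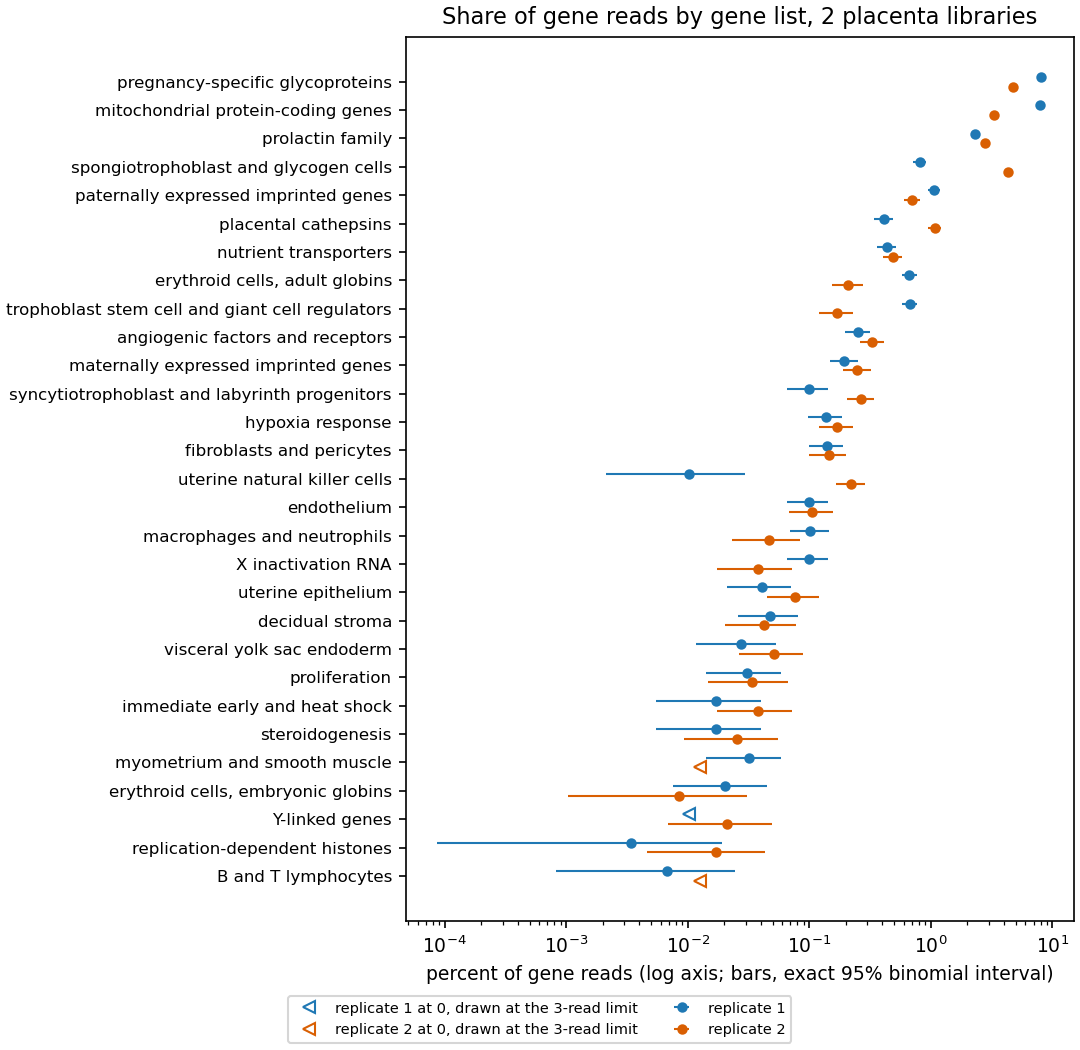
Share of gene reads held by each fixed gene list in placenta replicate 1 and replicate 2, on a log axis in percent, with exact 95% binomial intervals; open triangles mark lists at 0 in 1 library, drawn at the limit of 3 reads, and the 4 lists at 0 in both libraries are left out. Pregnancy-specific glycoproteins lie highest, at 8.12% and 4.74%, and uterine natural killer cell genes differ most in proportion among lists with reads in both, at 0.0102% and 0.220%.

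Markers of maternal tissue were sparse, apart from uterine natural killer cell genes in replicate 2 (52 reads, 0.220%). Decidual stroma genes held 14 and 10 reads, with Prl8a2 at 3 and 6, Prl3c1 at 7 and 0, Adamts5 at 1 and 4 and Hoxa10 at 1 and 0. Hand2, Pgr, Bmp2, Hoxa11 and Dio3 were at 0. Among granule proteins of uterine natural killer cells, Gzmg (0 and 33 reads) and Gzme (0 and 17) were higher in replicate 2, Gzmf had 2 and 2 and Prf1 had 1 and 0. Gzma, Gzmb, Gzmc, Gzmd, Ncr1, Klrk1, Klrb1c and Nkg7 had 0 reads, and the granzymes share reads, with a posterior SD of 8.75 reads for Gzmg. Uterine epithelium genes held 12 and 18 reads, from Muc1 (4 and 15, higher in replicate 2) and Cdh1 (8 and 3), with Ltf, Foxa2, Prss28, Prss29, Wnt7a and Lif at 0. Myometrium genes held 9.38 and 0 reads, with Des at 7 and 0, Smtn at 1.38 and 0 and Actg2 at 1 and 0, and Myh11, Cnn1, Acta2, Tagln and Oxtr were at 0.

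Adult globins were the most abundant of the blood, vessel and stromal genes. The adult erythroid list held 195 reads (0.665%) and 49 (0.208%), a mean of 10879 ± 7707 TPM (SD, n = 2), and Hba-a2 (94.9 and 26.2 reads) and Hba-a1 (84.1 and 15.8) were higher in replicate 1. Hbb-bs had 14.9 and 3.91 reads, Hbb-bt had 1.06 and 2.09, and Slc4a1, Gypa, Epb42 and Hemgn had 0. The alpha globins are near-identical, with a posterior SD of 42.9 reads each in replicate 1. Embryonic globins held 6 and 2 reads (Hbb-y 5 and 1, Hba-x 1 and 1, Hbb-bh1 0). Endothelial genes held 29 and 25 reads, of which the cadherin Cdh5 had 24 and 15, Pecam1 2 and 6, Eng 2 and 0 and Egfl7 0 and 1, with Tek, Tie1, Cldn5 and Emcn at 0. All 9 fibroblast and pericyte genes had a read, 41 and 34 in sum, with Vim at 12 and 4, Lum at 11 and 3, Col3a1 at 3 and 4 and Rgs5 at 2 and 7. Macrophage and neutrophil genes held 30 and 11 reads. Cd68 (23 and 1) was higher in replicate 1, Csf1r had 7 and 9 and Ptprc 0 and 1, and Adgre1, C1qa, C1qb, Lyz2, S100a8, S100a9 and Cd14 were at 0.

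No read of the skeletal muscle, pancreas, adipocyte or platelet lists was found. Skeletal muscle (Acta1, Ckm, Myh4, Myh1, Tnnt3 and Mylpf), exocrine pancreas (Cpa1, Cela3b, Prss2, Pnlip, Ctrb1 and Cel), adipocyte (Adipoq, Plin1, Cfd, Retn and Lep) and platelet genes (Pf4, Ppbp, Itga2b, Gp9 and Gp1bb) had 0 reads in both libraries, which by the limit of 3 reads allows shares of up to 0.0102% and 0.0127% for each list. Lymphocyte genes held 2 reads in replicate 1, 1 each of Ighm and Cd8a, with Cd3e, Cd3d, Cd4, Cd19, Cd79a and Ms4a1 at 0. Yolk sac endoderm genes held 8 and 12 reads, with Trf at 4 and 2, Afp at 2 and 4, Ttr at 0 and 1 and Apoa4 at 0 and 1, and Apoa1, Alb, Rbp4, Amn, Hnf4a and Apom at 0. Of all 333 list members found, 133 had no read in either library.

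Paternally expressed imprinted genes held more reads than maternally expressed ones. The former held 313 reads (1.07%) and 165 (0.700%), with Peg10, a retrotransposon-derived gene, at 172 and 49 (higher in replicate 1), the growth factor Igf2 at 108 and 64, Peg3 at 27 and 23, and Sgce at 2 and 6. Plagl1 (1 and 16 reads) was higher in replicate 2, and Snrpn, Usp29 and Zrsr1 had 0. The latter held 57 reads (0.194%) and 58.6 (0.249%), and none of the 5 compared passed. They included H19 (14 and 20.6 reads), Gatm (7 and 12), Meg3 (4 and 4) and Rian (4 and 6), while Osbpl5, Klf14 and Mirg had 0. Nutrient transporters held 127 reads (0.433%) and 115 (0.488%). The glucose transporter Slc2a1 had 24 and 29 reads and Slc3a2 had 8 and 10. The amino acid transporter Slc38a4 (9 and 27) and the iron exporter Slc40a1 (0 and 16) were higher in replicate 2, Slc38a1 (64 and 12) was higher in replicate 1, and Slc27a4 and Slc5a5 had 0.

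Of the remaining lists, mitochondrial protein-coding genes held the most reads, 2316 (7.89%) and 783 (3.32%). Of 11 compared, 5 were higher in replicate 2 and 5 in replicate 1, with mt-Co2 at 1076 and 43.5, mt-Atp6 at 363 and 0, mt-Co1 at 176 and 435, and mt-Nd1 at 279 and 82. These calls leave out the nuclear copies, with whose reads mt-Co2 had 1076 and 162, mt-Atp6 had 363 and 105, and mt-Co3, which without its copy was higher in replicate 2 (0.69 and 19), had 1768 and 19, so they depend on how reads were assigned. Angiogenic factors held 74 and 78, of which Flt1, a receptor of vascular endothelial growth factor, had 61 and 66, Vegfa 2 and 6, Eng 2 and 0 and Adm 3 and 0, with Vegfb, Vegfc, Angpt1 and Mmp9 at 0. Hypoxia response genes held 40 and 39.6 reads (Slc2a1 24 and 29, Ndrg1 3 and 1, Ldha 3 and 2.62, P4ha1 4 and 4), with Pgk1, Bnip3, Ankrd37 and Car9 at 0. Steroidogenesis genes held 5 and 6 reads (Cyp17a1 0 and 1, Stard3 1 and 1, Hsd11b2 1 and 2, Hsd17b2 1 and 1), with Hsd3b1, Hsd3b6, Cyp19a1, Hsd11b1, Hsd17b1, Akr1c18 and Fdx1 at 0. Proliferation genes held 9 and 8 (Cdk1 1 and 2, Pcna 0 and 2, Ccna2 4 and 0, Plk1 1 and 1), with Top2a, Ccnb1, Ccnb2, Aurka and Aurkb at 0. Immediate early and heat shock genes held 5 and 9 (Atf3 0 and 2, Jun 0 and 5, Dnajb1 2 and 0, Hsph1 1 and 1), with Fosb, Egr1, Hspa1a and Hspa1b at 0. Of 10 histone genes, 1, Hist1h2bc, had reads (1 and 4), and Hist1h4a, Hist1h4b, Hist1h2ac, Hist1h3b, Hist1h3c, Hist1h1e, Hist1h1c, Hist2h2ac and Hist2h3b were at 0. Xist, the RNA that coats the inactive X chromosome, had 27.3 and 9 reads and was higher in replicate 1 by reads, but its TPM, which rests on the transcripts the reads were assigned to, was 60.9 and 104, so its direction was not settled. Its antisense partner Tsix had 1.72 and 0. Among Y-linked genes, Ddx3y had 0 and 5 reads and Uty, Kdm5d and Eif2s3y had 0. The female sex in the labels may describe the dam, and the sex of each placenta was not determined.

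Many genes, trophoblast genes among them, differed between the 2 libraries by more than counting error. Among genes with at least 50 reads in the higher library, the largest ratios toward replicate 2 included Tpbpa (35.2-fold), Psg20 (39.5-fold), Prl7a2 (23.1-fold), the deubiquitinase gene Usp25 (3 and 110 reads, 32.5-fold) and the transcription factor gene Bhlhe41 (2 and 61 reads, 25.3-fold). Toward replicate 1 they included Prl2b1 (19.4-fold), the lysosomal protease gene Ctsd (98 and 3 reads, 27.3-fold), the pluripotency factor gene Nanog (51 and 1 reads, 33.3-fold), Prr15 (116 and 0 reads, at least 37.6-fold) and Selenof (59 and 0 reads, at least 19.1-fold). The other 10 were Gm28661 (0 and 119 reads), Gm15564, Gm10925 (0 and 105), Gm28438 (0 and 93) and Gm2830 toward replicate 2, and Gm28437 (1767 and 0), ENSMUSG00000045999, mt-Atp6, mt-Nd4l (63 and 0) and mt-Co2 toward replicate 1. ENSMUSG00000045999 and Gm42418, called in opposite directions, had the same posterior SD of 12.25 reads in replicate 1 and together held 2657 and 2431 reads (9.06% and 10.3%), so neither call is informative alone. The same holds for Gm10925 with mt-Atp6 (363 and 105 reads together, 3.36-fold toward replicate 1) and Gm28661 with mt-Co2 (1076 and 162, 6.43-fold). In all, 320 of 739 genes compared (43.3%) differed, 154 higher in replicate 2 and 166 higher in replicate 1, by the exact binomial test with Benjamini-Hochberg adjustment. The balance turned under other scalings, with 173 higher in replicate 2 and 161 in replicate 1 by median-of-ratios size factors, and 178 and 147 by total counts. For Tpbpa the adjusted p of the exact binomial test was 6.98e-172, and for Prl2b1 it was 4.74e-51. With no filter on reads 195 of 7761 genes differed, and with genes that share no read with another gene 208 of 535. Summed over the lists, 41 calls adjusted over all genes became 45 adjusted over the list alone.

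**Figure D2:**
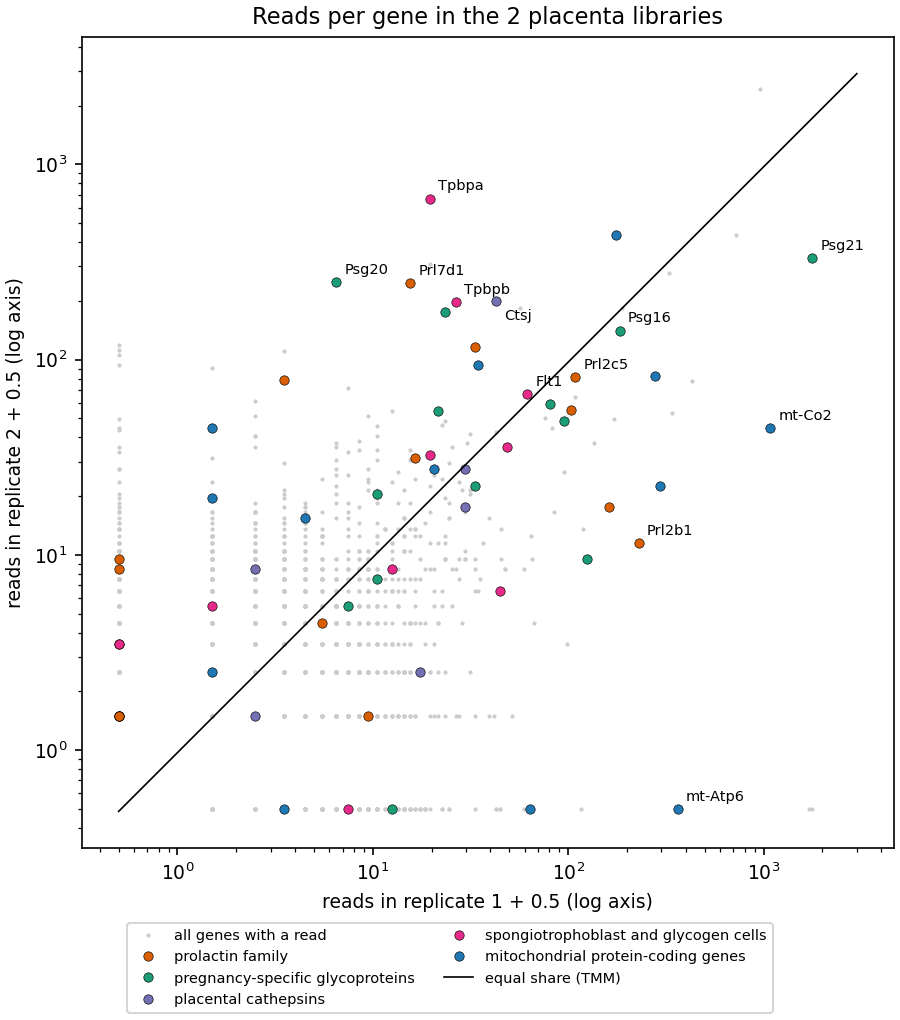
Reads per gene in placenta replicate 1 (horizontal) and replicate 2 (vertical), each with 0.5 added, on log axes; grey points are all genes with a read, coloured points the members of 5 lists, and the line marks equal shares after TMM scaling. Tpbpa (18.6 and 666 reads) lies far above the line, Prl2b1 (229 and 11) far below it, and Psg16 (183 and 140) close to it.

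By whole lists, only the trophoblast stem and giant cell list, whose reads came mostly from keratins, lay outside random lists. About 1 list outside is expected by chance among the 20 that could have been, and the other 13 could not, because their random range was 0 to 0. The list's median log2 ratio of replicate 2 over replicate 1 was -1.86, at percentile 0.610 of 10000 random lists matched on expression, whose central 95% ran from -0.95 to 0.04. All 7 members above 3 reads, among them Krt18, Krt8, Krt19, Krt7 and Gata3, had log2 ratios below 0, with a median of -0.96 when genes below 3 reads were set to 3. Over the 4 members with at least 10 reads, all keratins, the median of -2.50 lay inside the range of its own random lists, -4.54 to 3.62 (percentile 6.64). Uterine natural killer cell genes, 1 of the 13 lists, lay at percentile 99.8 over their 2 members with at least 10 reads. In 23 of the 33 lists the median was 0, where members without a read and members lying to either side met. Prolactin, pregnancy-specific glycoprotein and spongiotrophoblast lists had medians of 0, -0.44 and 0.08, with members at both extremes.

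Across genes, the relation between the 2 libraries depended on which genes were kept. Psg16, Prl2c5, Flt1, Slc2a1 and Peg3 had similar reads in both, while Psg21, Tpbpa, Prl7d1 and Prl2b1 did not. The biological coefficient of variation, the spread between libraries beyond counting error, was 1.03 over 739 genes (edgeR, estimateDisp). Over 100 resamplings of the genes another edgeR estimator, estimateCommonDisp, gave 1.02 to 1.14, which is not an interval of the 1.03. Pearson's r was -0.20 and Spearman's rho -0.16 over 7808 genes at 1 TPM or more in either library, and r was 0.48 and rho 0.47 over all 43346 genes without that filter, most of them at 0 in both. At this depth most genes passing the filter had a read in only 1 library, which pulls r below 0, so the negative value does not measure agreement, and genes are not independent replicates. Better-read genes showed no clear correlation either. Over the 734 genes with at least 10 unrounded reads summed, a filter chosen after seeing the data, r was -0.0721 and rho 0.0572. A read in both libraries was found for 2800 genes, against a mean of 3699 (3608 to 3781) in 100 simulated pairs that differed by counting error alone.

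**Figure D3:**
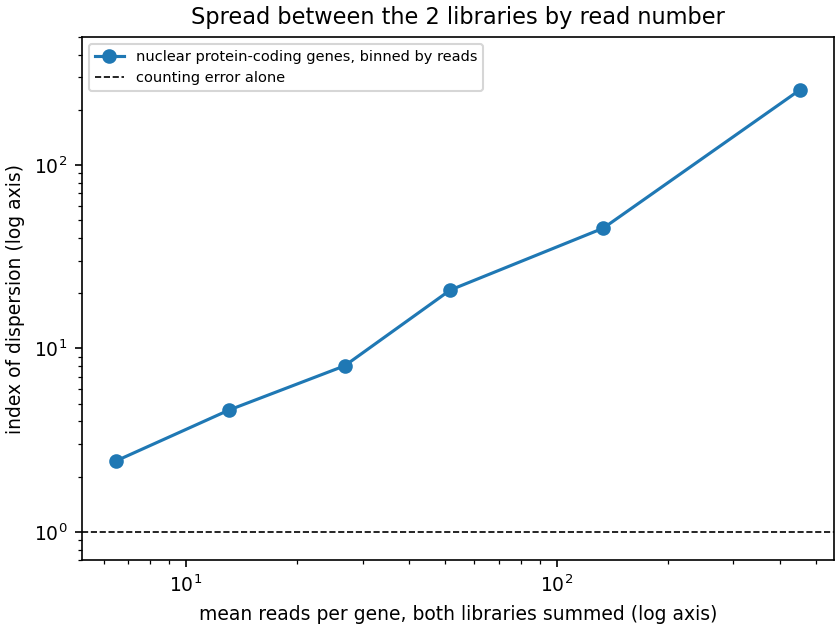
Index of dispersion between the 2 placenta libraries (vertical, log axis), the variance of reads divided by that of counting error, against mean reads per gene summed over both libraries (horizontal, log axis) in 6 bins of nuclear protein-coding genes; the dashed line marks counting error alone. The index rises from 2.44 at 5 to 9 reads to 256 at 200 or more reads. Its excess over 1, divided by mean reads, goes from 0.222 to 0.563 between these bins.

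Transcript estimates were examined for Flt1, Igf2 and 10 other genes, and the leading transcript was the same in both libraries for 7 of the 12. Flt1 reads fell mainly on Flt1-203 (chromosome 5, 147635159 to 147725988), a shorter form ending before the exons at the 3′ end of the full-length Flt1-202 (147561604 to 147726011). Flt1-203 held 61 and 47.7 reads, or 100% and 66.8% of the gene's TPM (83.4% ± 23.5, SD, n = 2), and Flt1-202 held 0 and 15.1 reads. Igf2-208, a processed transcript, led Igf2 with 47.7% and 77.0% of TPM from 24.4 and 25.8 reads, although a longer coding transcript had more reads (78.1 and 35.03). Psg16-204 (65.7% and 78.7%), Peg10-203 (86.8% and 40.2%), Slc38a4-202 (74.2% and 84.4%), Peg3-201 (71.9% and 78.6%) and Hbb-bs-201 (54.0% and 86.0%) also led in both. The last rested on 14.9 and 3.91 reads, and by posterior mean TPM its share in replicate 1 was 37.2%, below the 54.0% of Hbb-bs-202. For Hba-a2, Psg18, H19, Meg3 and Trf the leading transcript differed, with Hba-a2-202 at 89.7% in replicate 1 and 27.0% in replicate 2. In replicate 1 Hba-a2-202 had 84.06 reads, as did the near-identical gene Hba-a1, with a posterior SD of 42.9 reads for each gene. The Hba-a2 difference therefore depends on how reads were assigned. Meg3 and Trf rested on 4 and 4 reads and 4 and 2 reads, so their shares carry little information, and no test was made on shares.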

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

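The tests in this part were all chosen after the results were seen, and no biological explanation was tested, because the labels give 1 group.

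Reads on the phiX174 and tRNA rows, which lie outside the gene rows compared, exceeded the limit of 3 reads that a count of 0 allows. The phiX174 control took 154466 reads in replicate 1 and 149953 in replicate 2, and tRNA rows took 52 and 19.99 reads. Few reads in the alignments themselves stay open. The listed signal tracks of uniquely aligned reads, 56.9 and 48.8 megabytes, came to at least 281 bytes per read of the gene table. That divisor counted the phiX174 reads, 84.0% and 86.4% of all reads, so the bytes per mouse gene read were higher. The bytes that a read takes in a track were not measured. Counting on the wrong strand stays open as well, because antisense genes held 22.1% and 46.0% of the reads on 142 coding genes and the antisense genes covering at least 20% of their exon bases, from only 11.05 and 16 reads on the antisense genes and 38.95 and 18.78 on the coding genes, and the share of reads in genes with no exon on the opposite strand, at least 73.6%, lay near their share of protein-coding genes, 75.7%. A loss of reads between alignment and quantification may also explain the low totals, but the alignments were not analysed here.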

How the results depend on the processing

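The alternatives with deposited TPM, with genes of at least 10 reads for the correlation, with genes sharing no read and with a prior worth 1 read were chosen after seeing the data; the others were planned. Depth limited most results, since 1 read exceeded 1 TPM. Genes detected numbered 2805 with deposited TPM, 42274 with posterior mean TPM, whose prior gives nearly every gene a value, 117 at 10 reads in both libraries, and 5253 to 5362 with a replicate left out, by construction. The share of the 25 highest genes, mitochondrial genes included, was 4.67% with posterior mean TPM, 16.5% with deposited TPM including phiX174, and 35.5% to 51.4% with a replicate left out. The correlation reversed to 0.48 without a filter, where shared zeros enter, and to 0.98 with posterior mean TPM, and was -0.32 with a pseudocount of 0.1, -0.23 at 10 TPM and -0.0721 over genes of at least 10 reads. The coefficient of variation was 0.949 without a filter and, from DESeq2 gene-wise dispersions, 0.690 by their median and 1.36 by their mean; the cause was not tested. Genes differing numbered 195 without a filter, where more tests are adjusted for, and 208 among genes sharing no read, where fewer are tested; size factors gave 334 (173 higher in replicate 2), total counts 325 (178), and a ratio of 1.5 gave 325. Posterior mean TPM moved list levels by its prior. It gave 3518 TPM for the prolactin family, 6083 for pregnancy-specific glycoproteins, 626 for cathepsins, 2305 for spongiotrophoblast (from 28740), 202 for natural killer genes (from 1732), 366 for syncytiotrophoblast, 570.4 for the stem and giant cell list, 97.4 for decidua, 139.8 for uterine epithelium, 1199 for adult and 52.3 for embryonic globins, 292 for endothelium, 234 for fibroblasts, 98.0 for platelets, 57.3 for lymphocytes, 780.1 for paternally and 589 for maternally expressed imprinted genes, 411 for transporters, 270.1 for angiogenic factors, 446 for hypoxia, 225 for skeletal muscle, 40.3 for pancreas, 40.5 for adipocytes, 30.3 for X inactivation RNA and 9884 for mitochondrial genes. The share of Flt1-203 was 47.2% with it, and that of Hbb-bs-201 37.1%. With members of at least 10 reads, the median of the stem and giant cell list, -2.50, no longer lay outside random lists, as only 4 keratins remained, and that of natural killer genes did, at 10.84, from 2 genes at 0 reads in replicate 1 that the prior inflates (3.02 with 3 reads in place of 0). The median of the stem and giant cell list lay between -1.86 and -1.56 and outside random lists under the other scalings and priors. No paired analysis was possible because there is 1 group.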

Other observations

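The tests and lists of genes in this part were all chosen after the data were seen. Several lists, placental ones among them, were read more often than protein-coding genes of similar transcript length. Reads in both libraries were found for 12 of 13 pregnancy-specific glycoprotein genes, 10 of 23 prolactin-family genes, 6 of 8 placental cathepsins, 8 of 12 spongiotrophoblast genes and 10 of 16 nutrient transporters, against medians of 1, 2, 0, 1 and 3 in random lists matched on length. None of 10000 random lists reached the count of any of these 5 lists, nor that of mitochondrial protein-coding genes (10 of 13). For the trophoblast stem and giant cell list (6 of 13) 22 random lists did, for paternally expressed imprinted genes (7 of 13) 32, for fibroblast genes (7 of 9) 2, for maternally expressed imprinted genes (5 of 9) 20, for hypoxia response genes (5 of 12) 51, for adult erythroid genes (4 of 9) 93, for syncytiotrophoblast and labyrinth genes (5 of 14) 252 and for embryonic globins (2 of 3) 448, so the placental lists were not the only ones to stand out. Decidual stroma (2 of 10) and uterine natural killer cell genes (1 of 12) were within the random range, reached by 4956 and 5750 random lists. For the unread skeletal muscle, pancreas, adipocyte and platelet lists, random medians were 1, 0, 0 and 0, so counts of 0 were common at this depth. By share of gene reads these lists lay at percentiles 1.73, 11.9, 15.8 and 12.2 of random lists, so skeletal muscle alone was unusually low. The matching was on length and not on expression, so it does not separate placental genes from other abundant ones.

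A smaller set of genes was read about equally in both placentas. Of 47 genes with at least 20 reads in each library, 22 lay within 1.5-fold. They included the matrix protein genes Fn1 (187 and 183 reads) and Col4a1 (20 and 25), the protease gene Pappa2, which acts on insulin-like growth factor binding proteins (42 and 42), the antioxidant enzyme gene Gpx3 (30 and 37), the chaperone gene Hsp90b1 (21.6 and 23.9), the nuclear RNA Malat1 (328 and 276), and the trophoblast genes Psg16, Psg25 (80.2 and 59.2), Psg27 (33.3 and 22.3), Prl2c5, Cts3, Ceacam14, Ceacam5 (76.1 and 49.7), Flt1 and Krt8. Their TPM, which rests on the transcripts the reads were assigned to, was not always as close. It was 4529 and 1646 for Fn1, 8420 and 4880 for Prl2c5 and 386 and 647 for Flt1. For Psg16 it was close, at 7685 and 7296. Being chosen for similar reads, these genes do not estimate the agreement of the libraries. By contrast Nrk, an X-linked kinase gene with high placental expression, had 135 and 37 reads.

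The spread between the libraries was weighed against 3 explanations, each as the whole cause. A different cell makeup of the placentas is argued against by ribosomal protein genes, which every cell uses. With the reads of their pseudogenes added, 31 such genes had an index of dispersion of 14.8, against an upper bound of 1.55 under counting error. Among them were Rpl37a at 62 and 0 reads and Rps24 at 3 and 93. Without pseudogenes, 12 of the 31 had at least 10 reads, with an index of 22.1 against a bound of 1.95. Only 1 of these 12 shared no read with another gene. Rps24 was not among the 12, so its reads lay mostly on pseudogenes. Reads shared between similar genes are argued against by genes that share no read, of which 38.9% still differed, and a fixed number of duplicate reads per molecule by an index 105.0 times higher for genes with at least 200 reads than for genes with 5 to 9. Part of that ratio follows from the bins, because a gene's index cannot much exceed its reads. The excess of the index over 1, divided by mean reads, went only from 0.222 at 5 to 9 reads to 0.563 at 200 or more. Uneven amplification from few molecules may contribute, which stays open together with a part played by cell makeup, for example in Tpbpa and Krt18.

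Some mitochondrial genes and their nuclear copies were read in opposite libraries, while mt-Nd4 (34.5 and 93.4 reads) and its copy Gm28439 (14.5 and 33.6) were both read in both. The copies lie side by side on chromosome 1, from Gm28439 (start 24611535) to Gm29216 (end 24616197). Gm10925 is identical to mt-Atp6 over 678 bases and took 105 reads in replicate 2, where mt-Atp6 had 0, so the absence of mt-Atp6 there is consistent with reads assigned to the copy, and the pair had 363 and 105 reads together. The same holds for mt-Co3 in replicate 1, with 0.69 reads where Gm28437, identical over 783 bases, took 1767, but for the difference between the libraries it is argued against, since the pair had 1768 and 19 reads together, a 90.4-fold ratio after TMM scaling. The cause of such differences stays open, as for mt-Co2 and Gm28661 together (1076 and 162 reads) and mt-Nd3 and Gm28438 together (3 and 93).

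Gm42418 and ENSMUSG00000045999 had the same posterior SD, 12.25 reads in replicate 1, and together held 2657 and 2431 reads, or 9.06% and 10.3% of gene reads. Lars2 had 19 and 307 reads, and Gm15564 had 0 and 111. Both had posterior SDs of 0.54 and 0.81 reads in replicates 1 and 2, so they may share reads, although these SDs were small. Nanog had 51 and 1 reads, while the stem cell regulators Cdx2, Eomes, Elf5 and Esrrb had 0 in both.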
